A study of Mus musculus with 4 samples.

How the data were processed

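Total RNA was extracted with Trizol from rib cartilage cells of C57BL/6 mouse embryos at embryonic stage E17.5, and libraries were made by a standard Illumina protocol, per the labels. The genotype of each of the 4 libraries, 2 WT and 2 Trim28 KO, was taken from the labels. They state neither how the knockout was made nor the litter or batch of any sample. The authors deposited a table of raw counts per gene. Per the file headers, fragments of paired-end reads were counted over exons and summed by gene name with featureCounts 1.6.4 on GENCODE release M23 of mouse build mm10, with no option for strand, multi-mapping reads or reads that overlap several genes. Per the submitters' processing notes, Subread 1.6.4 and edgeR were also used. The aligner was not given in the sources used here.

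These settings affect some values. Reads that map to several places, or lie where genes overlap, were not counted, so genes with close copies or pseudogenes (ribosomal protein genes, Gapdh, Pgk1, Pgam1, Bglap and Bglap2, Hba-a1 and Hba-a2, protocadherins) have uncertain values. Strand was not used, so a gene and an antisense partner cannot be told apart. Loci that share a name were summed. Positions came from GENCODE release M21 on GRCm38, the same assembly as mm10. Gene names of 98.8% of the tested genes matched that release.

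The table held 55228 genes, of which 30326 had a count in at least 1 library. Totals ran from 18616896 to 20082123, and a count of 3 corresponded to 0.149 to 0.161 CPM. Intervals and floors cover counting error only. Genes were kept by edgeR's filterByExpr with its default settings, which left 16639. Counts were scaled by the trimmed mean of M-values (TMM), with factors of 0.939, 1.02, 1.04 and 1.00 for WT 1, WT 2, Trim28 KO 1 and Trim28 KO 2. Trim28 KO was compared with WT by edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust dispersion estimates and no covariate. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. "Higher", "rose", "lower" and "fell" refer to called genes. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. The common biological coefficient of variation was 16.3%. CPM are TMM-scaled.

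Before the data were examined, 35 gene lists, the tests, the alternatives and a rule for the genes to name were fixed. The rule took Trim28, the 8 called genes with the largest rise and the 8 with the largest fall among genes with a mean of at least 5 CPM and no overlap between genotypes (leaving out names of the form Gm with a number or ending in Rik), up to 4 members of each list with the smallest p-values, and 11 skeletal and growth genes. It gave 155 genes, and allowed fewer members to be named only for lists with no called gene. The text departs from it by naming only the first members by p-value of many lists that do have called genes, and this narrowing was made after the values, and those under the alternatives, were seen. Some genes that the rule took are not reported here. The values of every list member stand in the counts and tests of its list. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The lists covered cartilage matrix, hypertrophic chondrocytes, osteoblasts, skeletal stem cells, joint, perichondrium, Hedgehog, Wnt, BMP and TGF-beta signalling, cell cycle, p53, interferon, Zfp-numbered genes, imprinted, germline and 2-cell embryo genes, protocadherin beta genes, TRIM28 partners, Hox, adipocyte, protease, and hypoxia and glycolysis genes, 9 other cell types, and 4 groups tied to RNA quality or sex.

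The steps were tested on simulated counts drawn from these libraries' means and dispersions with 200 changed genes. In 16319 tested genes, 67% of 2-fold and 98% of 4-fold changes were called, and 5 of 170 calls were false. Of 20 unchanged simulated lists, 0 were called by camera at the preset correlation. Simulated genes were drawn independently, so this does not test the preset correlation on lists whose genes move together.

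The alternatives were relative log expression (RLE) factors, upper-quartile factors, library size alone, no filter on low counts, a stricter filter (5 CPM in 2 libraries), DESeq2 1.42.0, edgeR's exact test, limma-voom, a test against a log2 change of 1 (glmTreat), a replicate block, leaving out muscle, erythroid and leukocyte genes, and leaving out each library. Offsets that remove trends with gene length or with GC content and a crossed replicate block were chosen after the data were seen.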

Results

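Total RNA was sequenced from rib cartilage cells of C57BL/6 mouse embryos at embryonic stage E17.5, when the ribs hold growing cartilage that is in part being replaced by bone. 2 libraries came from wild-type (WT) embryos and 2 from Trim28 knockout (Trim28 KO) embryos. TRIM28 is a corepressor that zinc finger proteins with a KRAB domain bring to DNA, where it helps to form heterochromatin. The deposited counts of reads per gene summed to 20082123 in WT 1, 19493435 in WT 2, 18616896 in Trim28 KO 1 and 19903917 in Trim28 KO 2. Col2a1, the main collagen of cartilage, alone took 7.47%, 5.64%, 6.12% and 7.45% of the counts in the same order. The labels do not say whether the libraries of a genotype came from separate embryos, so p-values measure the spread between these samples, which in WT may be technical. The Trim28 KO libraries differed in Xist and Y-linked transcripts, so they were not repeats of 1 embryo. The counts of both WT libraries differed by more than sampling noise (chi-square of 30.6 per degree of freedom), as did those of both Trim28 KO libraries (24.6), and each library was counted as 1 sample.

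The comparison asked which transcripts differ between rib cartilage cells of Trim28 KO and of WT embryos. Trim28 itself, on chromosome 7 from 12999114 to 13031035 on the plus strand of GRCm38, stood, in TMM-scaled CPM (counts scaled to a common library size), at 225 and 186 in WT and at 51.1 and 54.5 in Trim28 KO. It fell 3.89-fold (log2 fold change of -1.96 ± 0.20, SE, n = 2 per genotype, adjusted p = 2.28e-07 by edgeR's quasi-likelihood test). This fall matched the labels of all 4 libraries. Part of the transcript remained in both Trim28 KO libraries, and its source was not tested. Of 16639 genes tested, 1438 were higher and 1460 lower in Trim28 KO, together 17.4% of those tested. By fitted value 741 of the higher and 824 of the lower genes differed at least 2-fold. The genotypes did not overlap in any of the 2898 called genes. They also did not overlap in 9646 of all tested genes (58.0%, where chance gives 33.3%). The counts fell to 702 higher and 572 lower without Trim28 KO 1, and to 906 higher and 807 lower without Trim28 KO 2. Tested against a minimum change of 2-fold, 214 genes were higher and 175 lower.

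Among called genes with a mean of at least 5 CPM, leaving out names of the form Gm with a number or ending in Rik, the largest rise was in Calb1. This gene, which encodes the calcium buffer calbindin, had 1 read in both WT libraries together and 511 in Trim28 KO, a ratio of 502 with a 95% counting interval of 89.6 to 19853 (exact, conditional on the sum). Lypd3 (log2 fold change of 6.05 ± 0.42), Mapt, which encodes the neuronal microtubule protein tau (4.88 ± 0.25), Cnnm1 (4.85 ± 0.35), Nell1, which encodes a secreted protein of bone and cartilage formation (4.81 ± 0.26), Azgp1 (4.60 ± 0.24), Chrdl2, a BMP-binding protein of the chordin family (4.52 ± 0.26), and Cox8b, a muscle-type subunit of cytochrome c oxidase (4.51 ± 0.58), followed. Within the same limits, the largest falls were in Mmp9, a matrix protease abundant in osteoclasts (-3.56 ± 0.24), Prg4, the joint lubricant lubricin (-3.56 ± 0.30), Lrrc15 (-3.45 ± 0.41), Vit (-3.00 ± 0.27), Ppm1e (-2.97 ± 0.31), Fxyd2 (-2.90 ± 0.30) and Itgbl1 (-2.82 ± 0.21). All these adjusted p-values from edgeR's quasi-likelihood test lay at or below 0.00821, the value of Cox8b. Lack of overlap between the genotypes was a condition for naming these genes, and it held for all 2898 called genes. On GRCm38, the risen genes start at 15.9 Mb of chromosome 4 (Calb1), 24.6 Mb (Lypd3), 49.97 Mb (Nell1), 100.01 Mb (Chrdl2) and 140.9 Mb (Cox8b) of chromosome 7, 104.2 Mb of chromosome 11 (Mapt), 43.4 Mb of chromosome 19 (Cnnm1) and 138.0 Mb of chromosome 5 (Azgp1). The fallen genes start at 164.9 Mb of chromosome 2 (Mmp9), 150.4 Mb of chromosome 1 (Prg4), 30.3 Mb of chromosome 16 (Lrrc15), 78.5 Mb of chromosome 17 (Vit), 87.2 Mb of chromosome 11 (Ppm1e), 45.4 Mb of chromosome 9 (Fxyd2) and 123.7 Mb of chromosome 14 (Itgbl1). Leaving out 1 library moved the log2 fold change of Calb1 to 7.86 without WT 1 and 10.99 without WT 2, that of Cox8b to 5.30 without WT 2 and 3.90 without Trim28 KO 1, and that of Lrrc15 to -4.24 without Trim28 KO 2.

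Of 24 cartilage matrix and chondrocyte genes, 6 fell, none rose and 18 did not pass the test (6 lower adjusted over the list alone). The falls were led by Epyc, a small proteoglycan of growth cartilage (-2.08 ± 0.22, adjusted p = 2.50e-07), Ucma (-2.45 ± 0.26), a matrix protein of young chondrocytes, Snorc (-1.26 ± 0.23) and Cnmd (-0.99 ± 0.24). Sox9, the transcription factor that specifies chondrocytes, stood at 404 ± 83 CPM in WT and 400.2 ± 51.1 CPM in Trim28 KO (SD, n = 2), and Col2a1 at 67572 ± 17055 and 66544 ± 11093 CPM, differences within the spread between libraries (log2 fold changes of -0.01 ± 0.22 and -0.02 ± 0.31). Acan, which encodes the proteoglycan aggrecan, had a log2 fold change of 0.55 ± 0.24 and was not called (adjusted p = 0.122), though DESeq2 called it (adjusted p = 0.0300). The median log2 fold change of the list was -0.21. The list was lower than other genes by camera (adjusted p = 9.31e-04), but not with an estimated correlation (adjusted p = 0.510), and without Trim28 KO 1 its median was 0.01 and its camera call was lost (adjusted p = 0.0566). Sox9 and Col2a1 changed sign under other settings and were never called. Without Trim28 KO 1, Cnmd was no longer called (adjusted p = 0.0591).

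Most of the listed genes of maturing cartilage and of bone fell. Of 12 hypertrophic chondrocyte genes, 9 fell and none rose (10 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -1.11. Mmp13, the collagenase of late hypertrophic cartilage, fell 5.99-fold from 546 ± 72 to 91.2 ± 12.4 CPM (SD, n = 2, adjusted p = 1.10e-08), and Ibsp (-2.19 ± 0.22), Runx2 (-1.22 ± 0.19), Spp1 (-1.28 ± 0.22), Col10a1, the collagen of hypertrophic chondrocytes (-0.98 ± 0.25), and the signal Ihh (-0.98 ± 0.26) also fell. Of 17 osteoblast genes, 4 of which are also in the hypertrophic list, 12 fell and 2 rose (13 and 3 adjusted over the list alone), with a median of -1.32. Bmp3 (-2.47 ± 0.23), Ifitm5 (-2.15 ± 0.25), Sp7, which encodes osterix (-1.32 ± 0.21), and Col1a1 (-1.53 ± 0.32) fell. The 2 that rose were Smpd3 (0.61) and Bglap2 (2.23), and Bglap2 is uncertain because it is nearly identical to Bglap. They were named after their values were seen. By camera both lists were lower than other genes (adjusted p = 4.08e-10 and 5.76e-12), and with an estimated correlation neither was called (adjusted p = 0.401 for each). Without Trim28 KO 1, Col10a1 (adjusted p = 0.114), Ihh (adjusted p = 0.190) and Col1a1 (adjusted p = 0.0507) were no longer called. In the same libraries markers of osteoclasts and red blood cells were lower in Trim28 KO and those of macrophages higher.

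**Figure D1:**
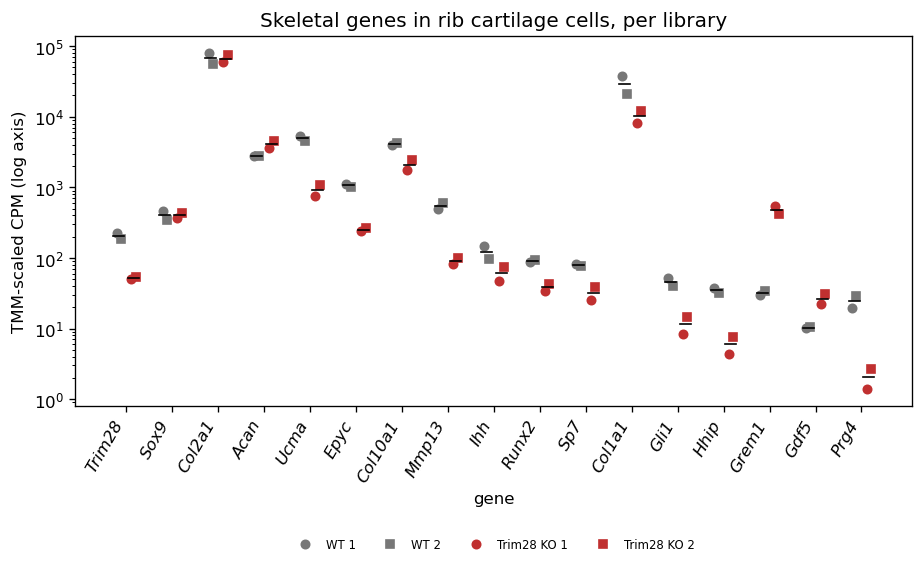
TMM-scaled CPM on a log axis for 17 genes (x axis) in each of the 4 libraries, with grey for WT, red for Trim28 KO, circles for replicate 1, squares for replicate 2 and a bar at the mean of each genotype (n = 2). Trim28 stands near 205 CPM in WT and 52.8 CPM in Trim28 KO, Sox9 and Col2a1 overlap between genotypes, and Mmp13 and Prg4 lie lower and Grem1 and Gdf5 higher in both Trim28 KO libraries.

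Of 24 skeletal stem and progenitor markers, 4 rose, 10 fell and 10 did not pass the test (7 higher and 10 lower adjusted over the list alone). Grem1, a secreted BMP antagonist, rose most (3.92 ± 0.23, adjusted p = 3.28e-11), and Apoe rose by 1.48 ± 0.22, whereas Lepr, the leptin receptor (-1.66 ± 0.20), and the Hedgehog effector Gli1 (-2.01 ± 0.24) fell. Pthlh, the parathyroid hormone-related signal of resting cartilage, had a log2 fold change of -0.18 ± 0.34 and was not called. The median was -0.33 and camera did not call the list (adjusted p = 0.229). Of 12 joint and articular genes, 5 fell and 2 rose (6 and 3 adjusted over the list alone). Prg4 (-3.56 ± 0.30) and Wnt4 (-2.06 ± 0.27) fell, and Barx1 (1.98 ± 0.29) and Gdf5, the signal of the joint interzone (1.37 ± 0.21), rose. The list had a median of -0.88 and a camera adjusted p of 0.0165, and its call was lost with an estimated correlation (adjusted p = 0.450), without Trim28 KO 1 (adjusted p = 0.0790), with no filter on low counts (adjusted p = 0.0559) and with a stricter filter (adjusted p = 0.156). Of 18 perichondrium, tendon and fibroblast genes, 7 fell and none rose (8 lower adjusted over the list alone), among them Mkx (-1.12 ± 0.20), Tnmd (-0.98 ± 0.20), Postn (-1.15 ± 0.24) and Col3a1 (-1.19 ± 0.27), with a median of -0.45 (camera adjusted p = 0.00254, but adjusted p = 0.401 with an estimated correlation). Col3a1 was no longer called without Trim28 KO 1 (adjusted p = 0.0764).

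Target genes of the signals that pattern cartilage moved in both directions. Of 12 Hedgehog target genes, 7 fell and none rose (8 lower adjusted over the list alone), with a median of -0.96. They included Hhip, a Hedgehog-binding feedback inhibitor (-2.52 ± 0.24), Gli1 and the receptor Ptch1 (-1.63 ± 0.22), each with an adjusted p of 2.44e-05 or less. The 7 also included Gas1 (-1.02) and Boc (-0.91), named after their values were seen. Both encode Hedgehog co-receptors, as does Cdon (0.06, not called), and their fall is not a readout of lower signalling. The count and the list test therefore mix such genes with readouts such as Gli1. Of 12 Wnt target genes tested, 5 fell and none rose (6 lower and 1 higher adjusted over the list alone), with a median of -0.60. The falls were led by Apcdd1 (-1.92 ± 0.29) and Notum (-2.29 ± 0.34), both inhibitors of Wnt signalling. Axin2 (-0.14) and Lef1 (-0.88), named after their values were seen, were not called. Of 16 BMP and TGF-beta target genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone), led by Grem1 and Tgfbi (1.59 ± 0.22), with a median of 0.47. The fall was in Ccn2 (-0.83). Id1 (0.03), Id2 (0.33), Id3 (0.14), Ltbp2 (-0.16), Smad6 (-0.07), Smad7 (-0.38) and Skil (-0.51) were not called. Ccn2 and these uncalled genes were named after their values were seen. By camera the Hedgehog and Wnt lists were lower (adjusted p = 1.28e-06 and 0.00396) and the BMP and TGF-beta list higher (adjusted p = 3.39e-05) than other genes. None of the 3 was called with an estimated correlation (adjusted p = 0.450 for Hedgehog, 0.529 for Wnt, and 0.401 for BMP and TGF-beta).

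Few genes of cell division were called. Of 28 cell cycle genes, 2 were called, Rrm2 (0.70 ± 0.19) and Plk1 (0.70 ± 0.19), both higher (2 higher adjusted over the list alone). Mki67, a marker of proliferating cells, was not called (-0.14 ± 0.20). The median was 0.13 (camera adjusted p = 0.205, and 0.0261 with no filter on low counts). Of 21 p53 target genes, 6 rose and 2 fell (9 and 3 adjusted over the list alone), led by the fall of Perp, a gene of desmosomes (-2.41 ± 0.33), and the rise of Gdf15 (1.68 ± 0.30). The cyclin-dependent kinase inhibitor gene Cdkn1a was not called (-0.06 ± 0.20). The p53 list had a median of 0.34 (camera adjusted p = 0.0809, and 0.0417 without Trim28 KO 1, 0.0174 with no filter and 0.0338 with GC-trend offsets). Rrm2 lost its call without WT 1 (adjusted p = 0.0844), Trim28 KO 1 (0.113) or Trim28 KO 2 (0.0568), and Plk1 without Trim28 KO 1 (0.0663) or Trim28 KO 2 (0.0999).

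Of 33 interferon response genes, 8 rose and none fell over all genes tested, and 19 rose adjusted over the list alone. The log2 fold change was above 0 for 32 of the 33, with a median of 0.79. Bst2, which encodes the antiviral membrane protein tetherin, went from 28.1 ± 3.3 to 68.8 ± 16.1 CPM (SD, n = 2, adjusted p = 6.55e-05), and Ifi35 rose by 0.89 ± 0.22, a call lost without Trim28 KO 1 (adjusted p = 0.125). Camera placed the list above other genes (adjusted p = 2.63e-06), and with an estimated correlation it was not called (adjusted p = 0.529). Macrophage markers were also higher in the Trim28 KO libraries. Of 24 hypoxia and glycolysis genes, 11 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.56. Pfkp, a phosphofructokinase (1.24 ± 0.21), and Egln3, a prolyl hydroxylase induced at low oxygen (1.01 ± 0.19), rose, and the carbonic anhydrase Car12 fell (-1.73 ± 0.20). Camera called this list higher (adjusted p = 3.39e-05), but not with an estimated correlation (adjusted p = 0.450). Pgk1, Pgam1 and Gapdh, 3 of the 11, have many processed pseudogenes, so reads that map to several places went uncounted. Of 8 adipocyte genes, Dgat2 (1.12 ± 0.23) and Pparg (1.05 ± 0.22) rose and none fell (2 higher adjusted over the list alone). The list median was 0.17 and it was not called (camera adjusted p = 0.208). Its median was below 0 without either Trim28 KO library (-0.13 without Trim28 KO 1 and -0.03 without Trim28 KO 2) and with no filter (-0.03).

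Of 17 matrix proteases and inhibitors, 7 fell and 5 rose (7 and 6 adjusted over the list alone). Mmp9 and Mmp13 fell, as given above, and Mmp3, the protease stromelysin, rose (4.67 ± 0.65). The Mmp3 value was 3.77 without WT 1 and 8.77 without WT 2. The list was not called by camera (median -0.06, adjusted p = 0.0678), and its call and sign varied. It was called without Trim28 KO 2 (median -0.33, adjusted p = 0.0126), without WT 2 (median 0.05, adjusted p = 0.0334), with a stricter filter (adjusted p = 0.0159) and with GC-trend offsets (adjusted p = 0.0484), and its median was 0.06 without Trim28 KO 1.

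Gene classes that TRIM28 is known to help silence showed few rises among the lists fixed beforehand. The clustered protocadherin gamma genes had 8 rises and 1 fall among 21. They were listed after values of such genes were seen, so this count is not an independent test, and they are described further below. The counts covered annotated genes only, so repeat elements were not examined. Of 351 tested genes named Zfp with a number, many of which encode KRAB zinc finger proteins, 10 rose and 18 fell (10 and 8 adjusted over the list alone), with a median of -0.15. Zfp991 (2.68 ± 0.30) and Zfp365 (1.92 ± 0.27) had the smallest p-values. Zfp993 (2.64), Zfp992 (2.39) and Zfp984 (1.67), named after their values were seen, were also among the 10 that rose. Camera did not call the list (adjusted p = 0.107, and 0.0247 with a stricter filter). Of 40 imprinted genes, 11 fell and 2 rose (13 and 2 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.00674, but adjusted p = 0.401 with an estimated correlation). The noncoding RNA Kcnq1ot1 (-1.36 ± 0.21) and the zinc finger gene Zim1 (-1.49 ± 0.23) fell. Of 37 germline genes, 9 could be tested, of which 4 fell and none rose (6 lower adjusted over the list alone), with a median of -0.82 (camera adjusted p = 0.0247, but adjusted p = 0.478 with an estimated correlation). Hormad2 (-2.40 ± 0.59) and Meioc (-2.65 ± 0.74) had the smallest p-values of that list. Hormad2 was called neither by DESeq2 (adjusted p = 0.0509) nor without WT 2 (0.144), Trim28 KO 1 (0.108) or Trim28 KO 2 (0.0695), and Meioc neither by DESeq2 (adjusted p = 0.140) nor without any of the 4 libraries (adjusted p from 0.0706 to 0.243; log2 fold change of -3.55 without Trim28 KO 2). The germline list lost its call without WT 2 (adjusted p = 0.287), Trim28 KO 1 (0.0566) or Trim28 KO 2 (0.142), and with no filter (0.621), where its median was -0.21. None of the 26 genes of the 2-cell embryo could be tested, since none had more than 3 counts in any library, so a difference was not detectable at this depth.

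Of 19 clustered protocadherin beta genes, Pcdhb22 rose (1.62 ± 0.20) and 3 fell (1 and 3 adjusted over the list alone), led by Pcdhb11 (-2.52 ± 0.57), whose call was lost without Trim28 KO 2 (adjusted p = 0.0850). The list had a median of -0.33 and was not called (camera adjusted p = 0.213). Reads shared between these similar genes went uncounted where they mapped to several places. Of 26 TRIM28 partners and silencing factors, 3 fell and none rose (3 lower adjusted over the list alone), with a median of -0.06 (camera adjusted p = 0.255) that was 0.01 when scaled by library size alone and 0.02 without WT 2. They were the remodeller genes Chd3 (-0.86 ± 0.21) and Atrx (-0.65 ± 0.20) and the silencing factor Tasor (-0.62 ± 0.19). Chd3 lost its call without Trim28 KO 1 (adjusted p = 0.151). Atrx lost it without WT 2 (0.305), Trim28 KO 1 (0.157) or Trim28 KO 2 (0.1603), and with length-trend (0.118) or GC-trend offsets (0.0595). Tasor lost it without any of the 4 libraries (adjusted p from 0.0551 to 0.186), when scaled by library size alone (0.0568) and with length-trend offsets (0.0664). Of 23 Hox genes tested, 3 fell and none rose (3 lower adjusted over the list alone), with a median of -0.24. The list was not called (camera adjusted p = 0.0900), but was with no filter (0.0442), length-trend (0.0396) and GC-trend offsets (0.0338). Hoxa6 (-0.85 ± 0.22) lost its call without Trim28 KO 1 (adjusted p = 0.0524) or Trim28 KO 2 (0.0975), and Hoxa9 (-0.94 ± 0.29) without any of the 4 libraries (adjusted p from 0.0738 to 0.130) and by DESeq2 (0.0722).

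Markers of other cell types that rib tissue can hold moved apart from each other. Of 15 macrophage and pan-leukocyte genes, 10 rose and none fell (11 higher adjusted over the list alone), with a median of 1.41. C1qa, a complement gene of macrophages, went from 15.1 ± 1.5 to 69.2 ± 26.9 CPM (SD, n = 2, adjusted p = 1.45e-05), and Adgre1, which encodes F4/80, rose by 1.42 ± 0.23. Of 10 osteoclast genes, 8 fell and none rose (10 lower adjusted over the list alone), with a median of -2.50, or -1.77 with a stricter filter. Mmp9, Acp5, which encodes tartrate-resistant acid phosphatase (-2.45 ± 0.20), and Atp6v0d2 (-2.79 ± 0.32) led the fall. Of 7 erythroid genes, 6 fell and none rose (6 lower adjusted over the list alone), with a median of -1.94, and Hba-a1 (-2.12 ± 0.20) had the smallest p-value, although its reads cannot be fully told from those of its near copy Hba-a2. By camera these 3 lists had adjusted p-values of 2.14e-09 (macrophage), 6.26e-16 (osteoclast) and 8.76e-12 (erythroid), and none was called with an estimated correlation (adjusted p = 0.450 for macrophage and 0.401 for both osteoclast and erythroid).

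Of 7 neutrophil genes, 3 fell and none rose (3 lower adjusted over the list alone), with a median of -2.68. Ltf, which encodes lactoferrin, had 64 reads in WT and 0 in Trim28 KO, which is at least 21.7-fold lower when Trim28 KO is set to the floor of 3 counts over the group. With Ltf set to that bound the list median did not change. Mpo fell by 2.68 on the log2 scale, which was not called without WT 2 (-1.47, adjusted p = 0.355), Trim28 KO 1 (adjusted p = 0.155) or Trim28 KO 2 (adjusted p = 0.0812) and was -3.29 without WT 1. The call of the list (camera adjusted p = 0.0155, but adjusted p = 0.529 with an estimated correlation) was lost without WT 2 (median -1.37, adjusted p = 0.234), and its median was -4.47 without WT 1, -4.71 without Trim28 KO 1 and -3.85 with no filter. None of 13 endothelial genes was called by edgeR, its exact test, DESeq2 or limma-voom, and 2 had an unadjusted edgeR p under 0.05 (0 adjusted over the list alone; Tek at -0.41 ± 0.19 and Robo4 at -0.43 ± 0.21 had the smallest p-values), with a median of -0.21 (camera adjusted p = 0.197, and 0.0234 without WT 2). Of 10 pericyte and smooth muscle genes, 4 fell and 1 rose (6 and 1 adjusted over the list alone), led by Actg2 (-1.52 ± 0.33) and Myh11 (-1.03 ± 0.23), the latter not called without Trim28 KO 2 (adjusted p = 0.0719). The list had a median of -0.66 (camera adjusted p = 0.0132, but adjusted p = 0.401 with an estimated correlation and 0.0530 with a stricter filter). Its summed counts still took a larger share of all counts in Trim28 KO (0.068% and 0.087%) than in WT (0.061% and 0.060%). Of 9 nerve and Schwann cell genes, 4 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -1.19 (camera adjusted p = 0.00674, but adjusted p = 0.418 with an estimated correlation). The gene that rose was S100b (0.79 ± 0.21). The summed counts of this list took a larger share of all counts in Trim28 KO (0.041% and 0.031%) than in WT (0.022% and 0.024%). The myelin gene Mbp fell (-1.27 ± 0.27), but was not called without WT 2 (adjusted p = 0.0742) or Trim28 KO 1 (0.0601). Of 4 epithelial and mesothelial genes tested, too few for a list test, Epcam fell (-2.18 ± 0.39; 1 lower adjusted over the list alone) and the median was -0.46.

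Of 19 skeletal muscle genes, Myog rose (1.39 ± 0.36) and Tnnt3 fell (-0.91 ± 0.22), and 17 did not pass the test (1 higher and 1 lower adjusted over the list alone). Muscle genes varied within each genotype. 16 of the 19 were higher in WT 2 than in WT 1 and 19 of 19 higher in Trim28 KO 1 than in Trim28 KO 2, with median ratios of 2.06 and 2.58. The list median was 0.62 and was not called (camera adjusted p = 0.213). With the crossed replicate block, chosen after the data were seen, the list was called (median 0.54, camera adjusted p = 1.64e-04). That block groups WT 1 with Trim28 KO 2 and WT 2 with Trim28 KO 1, the same split that these muscle genes show. It takes out that variation, so the call is not separate evidence of a difference between genotypes. The median of the list was 1.43 without WT 2, 1.14 without Trim28 KO 2 and -0.23 without Trim28 KO 1. Myog was not called without Trim28 KO 1 (adjusted p = 0.210) or with GC-trend offsets (0.0614) and stood at 2.04 without WT 2, and Tnnt3 was not called without Trim28 KO 2 (0.142).

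**Figure D2:**
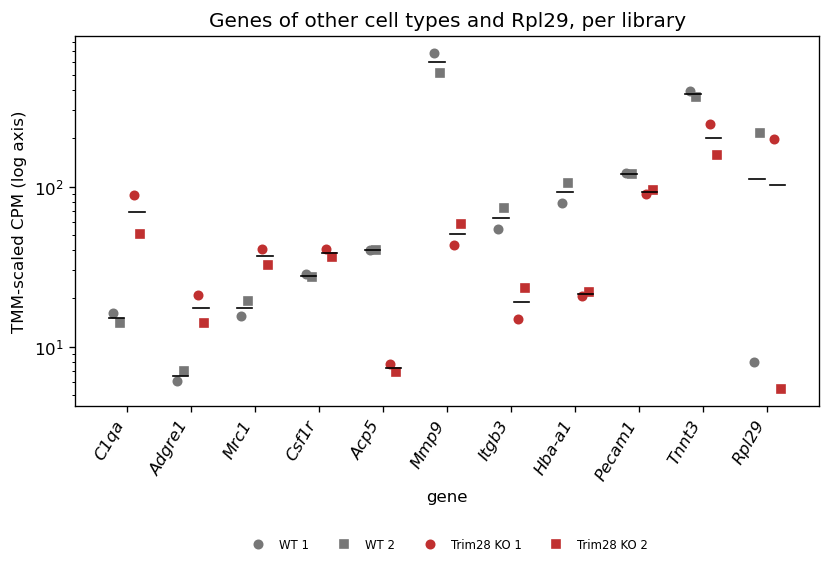
TMM-scaled CPM on a log axis for 10 markers of other cell types and the ribosomal protein gene Rpl29 (x axis) in each of the 4 libraries, with grey for WT, red for Trim28 KO, circles for replicate 1, squares for replicate 2 and a bar at the mean of each genotype (n = 2). C1qa, at 15.1 CPM in WT and 69.2 CPM in Trim28 KO, rises while Acp5 and Mmp9 fall, and Rpl29 splits the libraries within each genotype.

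Genes that respond to tissue handling also differed. Of 22 immediate early and stress genes, 9 fell and 4 rose (10 and 4 adjusted over the list alone), with a median of -0.37. Socs3 (-2.07 ± 0.24) and Fosb (-1.69 ± 0.21) had the smallest p-values, while the heat shock genes Hspa1a (1.11) and Hspa1b (1.04), named after their values were seen, rose. Camera called the list lower (adjusted p = 0.00109), but not with an estimated correlation (adjusted p = 0.450) or with no filter (adjusted p = 0.0608). Of 83 ribosomal protein genes, 18 fell and none rose (22 lower adjusted over the list alone), with a median of -0.48. Rps4x (-0.93 ± 0.20) and Rps6 (-0.88 ± 0.20) had the smallest p-values, and Rps6 was not called without Trim28 KO 2 (adjusted p = 0.0791). The list call (camera adjusted p = 7.31e-06) was lost with an estimated correlation (adjusted p = 0.535) and without WT 1 (median -0.17, adjusted p = 0.0946), and these genes have many pseudogenes, while reads that map to several places went uncounted. Of 21 mitochondrially encoded genes tested, only the transfer RNA gene mt-Tp was called (-0.62 ± 0.21; 0 adjusted over the list alone), a call lost without any of the 4 libraries (adjusted p from 0.0509 to 0.360), when scaled by library size alone, by DESeq2, by limma-voom and with length-trend or GC-trend offsets (adjusted p of 0.0797, 0.102, 0.0535, 0.180 and 0.0615 in that order). The list median was -0.28 (camera adjusted p = 0.161). It was called without WT 1 (-0.16, adjusted p = 0.0459) and Trim28 KO 1 (-0.49, adjusted p = 9.69e-04) and stood at 0.01 without Trim28 KO 2. None of the 5 tested sex-linked genes was called by edgeR or its exact test, 0 had an unadjusted edgeR p under 0.05 and 1 was called by DESeq2 and 1 by limma-voom (0 adjusted over the list alone), and their median (-0.77) and mean (0.78) differed in sign (camera adjusted p = 0.626, but 1.37e-04 without WT 1 and 2.73e-15, with a median of -7.34, without Trim28 KO 1; the median was 0.23 without Trim28 KO 2). Xist, which is transcribed from the inactive X chromosome, had 16, 16, 19 and 7127 reads in WT 1, WT 2, Trim28 KO 1 and Trim28 KO 2, and the Y-linked gene Ddx3y had 1891, 2219, 2214 and 12, so Trim28 KO 2 carried the pattern of a female embryo and the other 3 libraries that of males.

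Of the 35 lists, 33 had enough tested genes for a list test. Camera, with a preset correlation of 0.01 between genes, called 4 lists higher and 16 lower. With an estimated correlation no list was called (lowest adjusted p = 0.401, unadjusted p under 0.05 for 2 lists). Fry, which tests whether the genes of a list move on balance in 1 direction, called 2 lists, the osteoclast genes and the Zfp-numbered genes (unadjusted p under 0.05 for 12), and its test for changes in either direction called 24. In simulated data with the same libraries and 16319 tested genes, a list raised by 0.7 on the log2 scale was called by camera (adjusted p = 1.02e-25). It was not called with an estimated correlation (adjusted p = 0.174) or by fry (adjusted p = 0.344), so with 2 libraries per genotype these tests can miss such a change. The simulated genes were drawn independently, whereas estimated correlations in the real lists ran from -0.092 (pericyte and smooth muscle) to 0.927 (neutrophil). The simulation therefore cannot tell whether the preset correlation calls such lists too readily, or why their calls were lost.

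**Figure D3:**
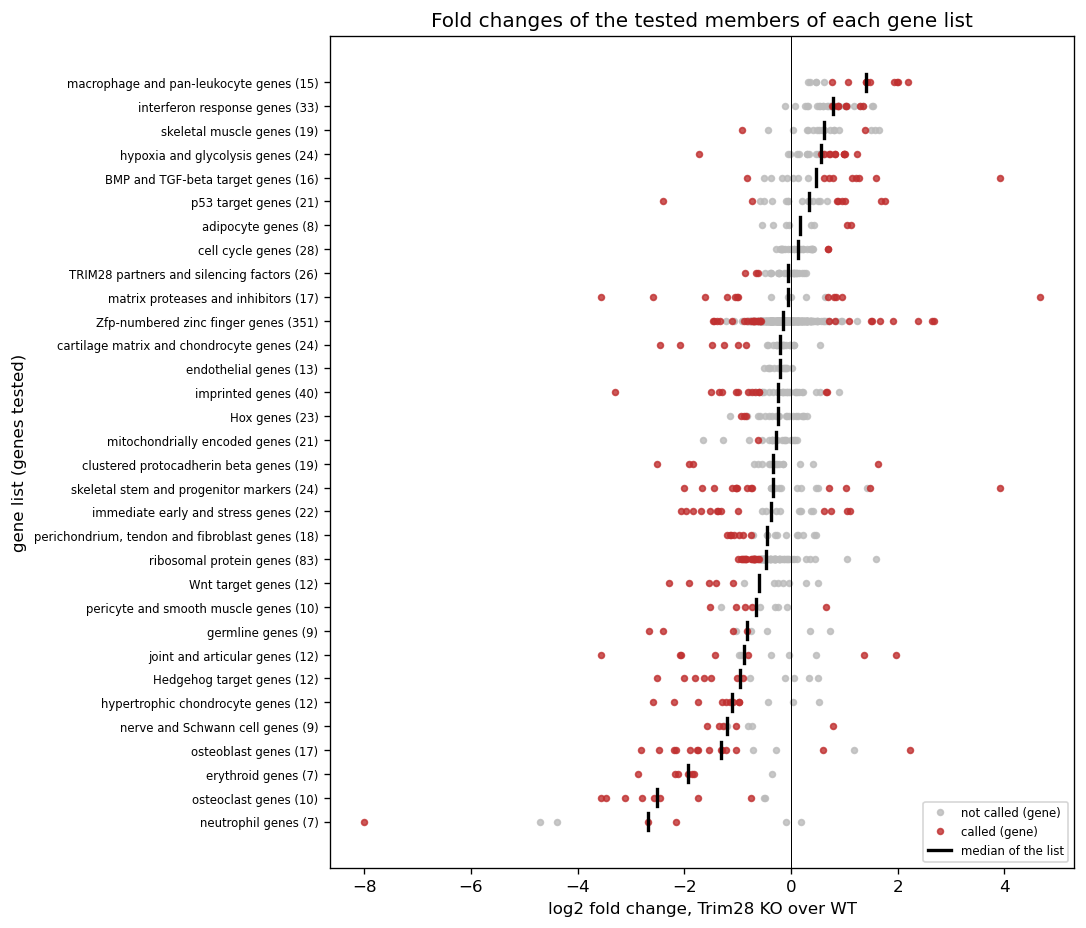
Log2 fold change of Trim28 KO over WT (x axis) for each tested gene of 32 gene lists (y axis, with the number of genes tested), in red where the gene was called at an adjusted p under 0.05 by edgeR and in grey where it was not, with a black line at the list median; the sex-linked list is left out. Medians run from -2.68 in the neutrophil genes to 1.41 in the macrophage and pan-leukocyte genes, and the neutrophil gene at the far left, Ltf, had no reads in Trim28 KO.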

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

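The length-trend and GC-trend offsets and the crossed replicate block were chosen after the data were seen. Trim28 was lower under all 18 alternatives (log2 fold change from -2.07 to -1.79). In none of them was a called gene called in the opposite direction. Among the 89 called genes that the text names by the rule, 0 changed sign. For other called genes a change of sign without a call was not checked. The genes higher and lower numbered 1438 and 1460, against 214 and 175 with glmTreat, which by its construction asks for a larger change. Leaving out 1 library gave 702 to 1442 higher and 572 to 1406 lower genes, with a lone library assumed to vary like the others. The other alternatives kept both counts within 1.5 times, and the highest share of higher genes among scalings was 57.4%, with library size alone (main 49.6%). Camera called 20 lists, against 0 with an estimated correlation and 2 by fry, tests that also missed a raised list in simulated data. The simulated genes were drawn independently, so the simulation cannot tell why the calls of the real lists were lost. Of 89 called genes that the text names by the rule (those named after their values were seen were not included), 79 kept their call wherever tested under the alternatives with all libraries other than glmTreat, 66 when each library was left out and 45 with glmTreat.

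The replicate numbers are shared by the genotypes, but deviations of same-numbered libraries did not go together (correlation -0.107), so the numbers were not taken to pair samples. With the replicate block 1477 genes were higher and 1444 lower, and 4 named genes (Cox8b, Ihh, Notum, Myog) were not called. With the crossed replicate block 1593 were higher and 1747 lower.

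Of the 12 results that changed sign, only the cartilage list had been called, and the cause was not tested. With library size alone the log2 fold change of Sox9 was 0.058, that of Col2a1 0.050 and the median of TRIM28 partners 0.0063. With no filter Sox9 was 0.013, Col2a1 0.0042 and the adipocyte median -0.031. Col2a1 was 0.051 with length-trend and 0.0098 with GC-trend offsets. Leaving out 1 library gave ranges of -0.18 to 0.23 for Sox9, -0.23 to 0.28 for Col2a1, -0.53 to 0.20 for the log2 fold change of Pthlh, -0.17 to 0.046 for Cdkn1a and -0.32 to 0.031 for Mki67. For list medians the ranges were -0.50 to 0.012 (cartilage), -0.13 to 0.016 (TRIM28 partners), -0.13 to 0.18 (adipocyte), -0.33 to 0.063 (proteases), -0.23 to 1.43 (muscle), -0.49 to 0.0053 (mitochondrial) and -7.34 to 0.23 (sex-linked). Genes and lists removed by the stricter filter, or left out with the muscle, erythroid and leukocyte genes, had no value there, and DESeq2, the exact test, limma-voom and glmTreat gave no list tests. Depth limits genes near 3 counts per library, such as the 2-cell embryo genes.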

Other observations

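The lists and single genes in this part were chosen after gene values were seen, and the tests on sex, other cell types, Rpl29 and Tpsab1, and other groupings of the libraries were chosen after the results were seen. Of 21 cholesterol synthesis genes, 19 rose and none fell (20 higher adjusted over the list alone), with a median log2 fold change of 1.12. Mvd rose by 1.70, Sqle by 1.54 and Dhcr7 by 1.44. Camera called the list higher (adjusted p = 1.43e-20 over the 6 lists made later). With an estimated correlation its p was 0.00918, or 0.0341 adjusted over those 6 lists. This is a smaller family than the 33 lists fixed beforehand, where the osteoclast p of 0.0125 was not called (adjusted p = 0.401). Of 21 clustered protocadherin gamma genes, the neighbours of the beta cluster, 8 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.86 and Pcdhgb2 highest at 3.48. Camera called this list (adjusted p = 5.42e-05), but not with an estimated correlation (adjusted p = 0.230), and Pcdhg variants share exons whose reads were not counted. Values of genes in this list had been seen before it was made, so its counts and tests are not independent support for a rise. Olfr1349, an olfactory receptor gene, had 0 reads in WT 1 and WT 2 and 52 and 56 in Trim28 KO 1 and Trim28 KO 2. This is 35.3-fold higher when WT is set to 3 counts over the group. The lower limit of the exact 95% counting interval was 28.3-fold. Within 10 Mb of Trim28, 34 of 186 genes were called (18.3%), against 2842 of 16256 elsewhere (17.48%; Fisher's exact test, 2-sided p = 0.771, odds ratio 1.06 with a 95% interval of 0.704 to 1.54).

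Some called genes raised hypotheses that were tested on other members of the same pathway, leaving out the genes that raised them. Chac1, Slc1a4, Sesn2 and Ddit3 are targets of ATF4, the transcription factor of amino acid and protein stress. Of 31 further targets 17 rose and none fell (20 higher adjusted over the list alone; 1-sided Fisher's exact test, p = 6.27e-11), with a median of 0.67, which is consistent with a wider rise of this program. Trib3 rose by 2.67, Stc2 by 2.11 and Fgf21 by 3.75. In the same libraries 9 of 22 immediate early and stress genes fell and 4 rose, with Hspa1a higher by 1.11 and Hspa1b by 1.04, and whether handling of the tissue adds to the ATF4 rise was not tested. Ddit3 is also a member of the immediate early list and Sesn2 of the p53 list, so rises in those lists are not separate from the genes that raised this hypothesis. Atp6v1h and Gpnmb act in lysosomes. Of 40 further lysosomal genes 19 rose and 1 fell (24 and 1 adjusted over the list alone; 1-sided Fisher's exact test, p = 1.25e-10), with a median of 0.55, and Neu1 rose by 1.49 and Gusb by 1.31. Macrophages are rich in lysosomes, so their contribution is not excluded. The Fisher tests in this paragraph count genes as independent, which they are not, so their p-values do not measure the spread between samples. By camera with an estimated correlation, the p-values of the ATF4 and lysosomal lists were 0.0143 and 0.0170 (adjusted p = 0.0341 for each over the 6 lists made later). Both were larger than the osteoclast value that was not called over 33 lists. Plin4 coats lipid droplets, Fabp3 binds fatty acids and Cox8b belongs to the respiratory chain, and their rise raised the hypothesis of a wider rise in fatty acid use. Of 20 tested genes of fatty acid oxidation none rose and 4 fell (0 and 4 adjusted over the list alone; 1-sided Fisher p = 1 for a rise; median -0.02), so the rise of those 3 genes did not extend to this list.

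Of the 3 ways to split the 4 libraries into pairs, 1, the split by genotype, gave as many called genes (2898). The highest of the others gave 0 by edgeR, with 154 genes at an unadjusted p under 0.05. With 3 splits no share under 0.05 can be reached.

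The library Trim28 KO 2 had the transcripts of a female embryo and the other 3 those of males. If that difference in sex had produced the called genes, a comparison of the 3 male libraries should call few. It called 1713 genes, which argues against sex as the source of the calls as a whole, though that comparison held 1 Trim28 KO library, assumed to vary like the 2 WT libraries that gave the spread. For single genes, the share due to sex was not tested.

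Macrophage markers rose while osteoclast and erythroid markers fell. A lower share of chondrocytes would raise the other cell types alike. The macrophage median exceeded the endothelial median by 1.62 (2-sided permutation test over genes, which are not independent replicates, p = 9e-05). Macrophage genes moved together (estimated correlation 0.924) and the medians were known beforehand, so this p is not independent support. A lower share of chondrocytes would not by itself lower osteoclast markers. Their median of -2.50 argues against it as the only source. Whether it added to the rise of macrophage markers was not tested. More macrophages of an unchanged kind stay open, since C1qa rose 5.61 standard errors more than Csf1r, but osteoclasts and their precursors also express Csf1r. Fewer osteoclasts and lower levels per cell cannot be told apart in bulk RNA, where 8 of 10 markers fell and the log2 fold changes of all 10 spanned 3.08.

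Rpl29 had 150, 4253, 3859 and 108 reads in WT 1, WT 2, Trim28 KO 1 and Trim28 KO 2, so it differed over 10-fold within each genotype. Tpsab1, a mast cell tryptase, had 1, 27, 26 and 1 reads in the same order. It split the libraries in the same way, but with 1 read in the lower library of each genotype the size of its difference is uncertain. Reads counted at the pseudogenes Gm10709 and Gm17669 in place of Rpl29 would keep the sum level, but it was 20.8 times higher in WT 2 than in WT 1. Reads that match several copies went uncounted, so a loss of such reads stays open. The other mast cell genes summed to 1.22 times as many reads in WT 2, and muscle genes had a median ratio of 2.06, which argues against mast cell content for Tpsab1 and muscle in the dissection for Rpl29. A strain variant that segregates between embryos may be the source of both and also stays open, since counts hold no sequence, and no biological explanation other than cell content was tested. Entpd4 had 213, 64, 56 and 190 reads in the same order.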
